A study of Mus musculus with 18 samples.

How the data were processed

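The measurements are array comparative genomic hybridisation, in which the DNA of an animal and of a reference are labelled with different dyes and hybridised together, so that the ratio of the dyes at each probe reads relative copy number. Tail DNA of 9 mice of the C57BL/6JNrs strain was compared with the DNA of reference male mouse 14 of the same colony on 18 arrays, 2 per animal with Cy3 and Cy5 exchanged. The groups were a male parent, a female parent and 7 offspring, as the labels name them. The 2 arrays of an animal hold the same DNAs and were averaged to 1 value, so the animal is the replicate. No arrays were identical: correlations between arrays of the same dye orientation reached at most 0.816 with the animal in Cy5, and the lowest was -0.11.

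Per the file headers, the arrays were read with Agilent Feature Extraction 12.1.0.3 under its protocol for copy number arrays, and probe positions refer to build mm9 (NCBI37). The deposited scanner files hold an intensity for each dye that was background-subtracted and dye-normalised by that program, per the file headers, with median spot and background intensities, quality marks, and a log10 ratio of red over green. The deposited series table holds a log2 ratio per spot whose steps are not given in the sources used here. Set against the scanner values, each of its columns read reference over animal, with correlations of 0.963 to 0.998 and column medians from -0.000131 to 0.0123; its centring and any adjustment stay unknown. It was used, with its sign turned, as an alternative.

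Each array has 148626 spots, of which 6563 are controls. Controls and spots marked as non-uniform or as population outliers were left out, between 95 and 351 marked spots per array. The remaining spots were averaged to 138014 probes. The log2 ratio of processed signals was turned to animal over reference and centred on the median of each array. Median net signals were 417 to 910 in Cy3 and 639 to 1280 in Cy5, and between 91 and 380 spots per array were not well above background in at least 1 channel. For arrays, the number of animals and of probes per region limits the precision.

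Probes no more than 10 kb apart formed 6350 candidate regions, of which 3747 were lone probes and 2569 had at least 5 probes (median 53 probes, 7.16 kb). Ratios within a region were segmented by optimal partitioning with a penalty of 2 times the noise variance times the logarithm of the probe number (at least 20). A segment was called with at least 5 probes, an absolute mean log2 ratio of at least 0.25, and at least 0.125 with the same sign in each dye orientation. The same procedure was run on the difference between orientations divided by 2, in which copy number and other effects of the DNA cancel. Its mean over animals, the dye effect they share, was subtracted first, and the rest was rescaled for that subtraction. The rule on single orientations could not act there. The calls thus count noise of dyes and arrays that the animals do not share. Overlapping calls of different animals were joined to merged regions.

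For tests across the array, 13607 blocks of 10 consecutive probes (at least 5) were averaged and fitted with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The 7 offspring were tested against 0, which leaves out the spread of the reference, against the 2 parents, and each animal against the other 8. The parents were compared without a p-value, at 0.25 in the mean and 0.125 in each orientation. Transmission was tested per merged region with an exact two-sided binomial test. Slides and scan days came from the file headers: both parents lay on slide 1, the offspring on slides 2 to 5, and scan day 1 held slides 1 and 2. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0.

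The text names the 10 merged regions called in the most animals, with ties ordered by absolute mean, the 10 offspring segments without a parental call of the same sign that differed most from the parents, and the 10 merged regions with the largest difference between parents. This rule, the tests and most alternatives were fixed before the data were examined. Alternatives were normexp background correction (offset 50, on median signals), loess within arrays, the deposited table, marked spots kept, dim probes left out, other thresholds, probe minimums, penalties, gaps and block sizes, slide as a random block, single dye orientations, and leaving out each offspring. Added after seeing the data were a probe length correction, removal of 2 components, scan day as a block, leaving animals out of the count of calls, and joining of neighbouring segments. The 2 components were the largest patterns over animals in the block means of these same data. Their removal takes out, by construction, the differences between animals that they hold. A correction for base composition and tests of 7 gene lists needed a sequence or an annotation of mm9, which was not used here, so no gene is named.

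The procedures were tested on simulated data. Segments were put into the difference between orientations less its mean over animals, only in the larger of the 6350 candidate regions. A segment counted as recovered if any call of its sign overlapped it, and the rule on single orientations could not act. Of 200 segments of 5 probes shifted by 0.3, the caller recovered 87.5%, and 99.5% of those with 10 probes. These segments had the same shift at every probe, which real segments need not have. Of 200 of 13607 blocks shifted by 0.3, limma recovered 99.0% in the test of offspring against the reference, 90.0% in that against the parents, and 68.5% in that of 1 animal against the other 8, where a shift of 0.15 was recovered in 0%.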

Results

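The series examined DNA copy number in a family of C57BL/6JNrs mice with an array of dense probes around positions picked in a first screen with another array. The family held a male parent, a female parent and 7 offspring, each measured on 2 dye-swapped arrays against reference male mouse 14 of the colony. The series title names exposure of males to 0.05 mGy per day of gamma rays for 400 days, whereas the design text calls the male of this family non-irradiated. The labels thus disagree, and with 1 family there is no comparison of exposed with unexposed animals. The probe positions were chosen on DNA of mice of this series, so the regions are not an independent sample of the genome. Positions below are of build mm9.

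The exchange of dyes shows which differences follow the DNA. After both arrays of an animal were turned to read animal over reference, their correlation across probes ranged from -0.56 in offspring 6 to 0.30 in offspring 5, with a median of -0.15. Probe-specific dye effects were shared by all animals: the difference between orientations correlated between animals with r of 0.626 to 0.844. After the mean dye effect was subtracted, the 2 orientations of an animal correlated with r of 0.236 to 0.83. These correlations are across probes, which are not independent replicates. The noise between neighbouring probes had an SD of 0.043 to 0.076 on the log2 scale.

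Copy number segments were sought in each animal alone. In total 572 segments were called, 458 gains and 114 losses relative to the reference. Gains were short, with a median of 6 probes and 484 bp and a median log2 ratio of 0.45. The animals differed widely: gains numbered 105 in offspring 5, 90 in offspring 2, 89 in the female parent, 83 in offspring 7 and 77 in offspring 1, but 7 in offspring 4, 3 in offspring 3, and 2 each in offspring 6 and the male parent. Animals with 77 or more gains also had the highest noise between neighbouring probes, with SDs of 0.054 to 0.076. In the others it was 0.043 to 0.051. Of the losses, 76 lay in a stretch of chromosome 14, with a median of -0.57, and 38 lay elsewhere, with a median of -0.29, of which 29 were in offspring 2. Without offspring 2 the losses numbered 71. On the difference between orientations, less the dye effect that the animals share, the rules other than that on single orientations gave 3 calls. These count unshared noise of dyes and arrays but not effects that go with the DNA of an animal. The calls fell into 269 merged regions, of which 157 were called in 1 animal and 2 in all 9. A minimum of 3 probes gave 2369 segments and a minimum of 10 gave 27.

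**Figure D1:**
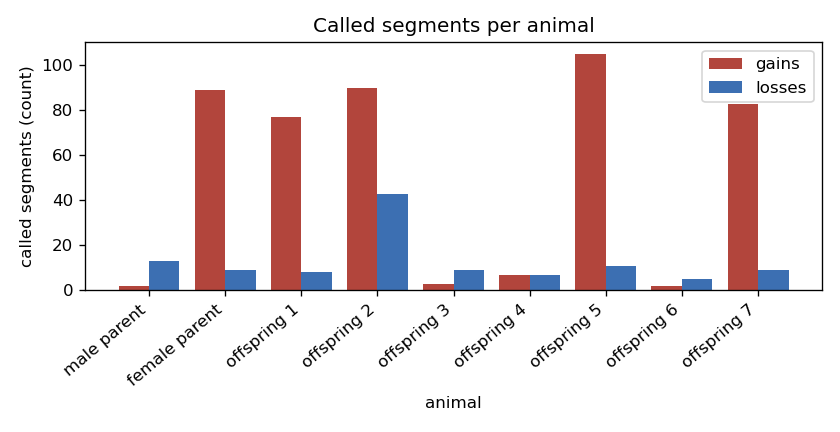
Number of called gains and losses (bars, from 0) in each of the 9 animals. Gains range from 2 in the male parent to 105 in offspring 5, and offspring 2 has 43 losses.

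Of the 10 merged regions called in the most animals, 7 lay on chromosome 14 and were lower than the reference. Both regions called in all 9 animals were 54151194 to 54154880, at -0.51 ± 0.04 (SD, n = 9), and 53975729 to 53991991, at -0.45 ± 0.06. Called in 8 animals were 53714075 to 53721586, at -0.83 ± 0.03, 54176697 to 54182168, at -0.60 ± 0.07, 54158539 to 54167581, at -0.48 ± 0.06, and 54322612 to 54338299, at -0.44 ± 0.05. The region 53753178 to 53763828, called in 6 animals, was at -0.85 ± 0.04. A region of chromosome 8, 102235347 to 102239768, was called as a gain in 6 animals and lay at 0.29 in the female parent and at 0.29 to 0.36 in offspring 3 to 7, against -0.06 in the male parent, -0.02 in offspring 1 and 0.03 in offspring 2. The remaining pair were gains called in 4 animals, at chromosome 2, 8488287 to 8488662, with 1.01 in offspring 2 and 0.72 in the female parent, and at chromosome 9, 32903488 to 32903901, with 0.90 in offspring 2 and 0.61 in the female parent.

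The comparison of the offspring with the reference asks where their mean differs from it. The offspring were lower in 22 blocks and higher in 1. Of the lower blocks, 20 lay between 53424325 and 54371399 on chromosome 14, where the offspring means ranged from -0.85 to -0.14, and all 9 animals, the parents included, were below the reference in each of the 20. Over the 192 probes of this stretch the mean was -0.46 ± 0.02 (SD, n = 9). The nearest regions with at least 5 probes on each side were at 0.01 ± 0.02 (51736850 to 51745092) and 0.01 ± 0.02 (54400955 to 54410477). The highest adjusted p of the 20 blocks was 0.000399 (limma, n = 7). The other blocks, named because they were few, were chromosome 3, 108660386 to 108661268, at -0.07 (SE 0.01, adjusted p = 0.023), chromosome 11, 112961382 to 112962725, at -0.17 (SE 0.02, adjusted p = 0.0174), and chromosome 13, 95707465 to 95708789, at 0.15 (SE 0.01, adjusted p = 0.000449), all from limma. The chromosome 11 block was uneven: it lay at -0.22 to -0.18 in the female parent and offspring 3 to 7, against -0.12 in offspring 2, -0.03 in offspring 1 and 0.00 in the male parent. Without overlap it parted the animals with high X probes from the others, as 14.9% of all blocks did, a split that nearly coincides with scan day. In the chromosome 13 block the male parent was at 0.25 and the female parent at 0.00, and the offspring lay between them at 0.09 to 0.20. At an unadjusted p under 0.05 there were 2030 blocks. The reference was a single mouse, whose own spread is not part of this test, and a ratio does not tell inherited copies from changes in part of the cells.

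**Figure D2:**
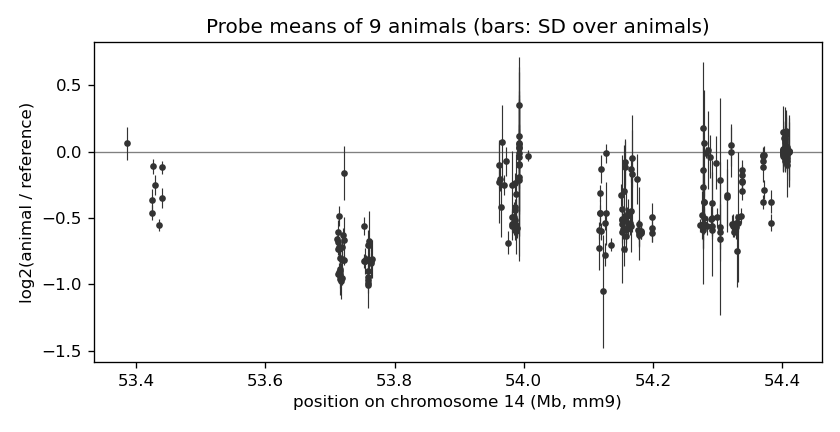
Log2 ratio of animal over reference (vertical axis) at each probe along chromosome 14 (horizontal axis, Mb, mm9). Points are means of 9 animals and bars are SDs over animals. Most probes from position 53424325 to 54371399 lie below 0, and those from 54400955 on lie near it.

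The parents were compared because positions at which they differ can segregate. The female parent was higher than the male parent in 136 blocks and lower in 2, with 1 animal each and hence no test. Loess within arrays gave 114 higher and 17 lower, and with 2 components removed, chosen after seeing the data, 1 was higher and 2 were lower. The latter fall is largely built in, since the components were taken from these same animals. The 2 lower blocks, named because they were few, adjoin on chromosome 3: 25415551 to 25432405 differed by -0.74 and 25432440 to 25435605 by -1.55. In the first block the female parent was at -1.57, -3.69 and -1.89 at the probes from 25421508, 25425639 and 25428636. At the other probes of that block the female parent lay between -0.11 and 0.07. In the second block the female parent was at -1.50 and offspring 3 to 7 at -1.50 to -1.59, against 0.05 in the male parent and 0.04 in offspring 1 and 2. No segment was called there, since its probes vary; with neighbouring segments joined, an alternative chosen after seeing the data, it was called in 6 animals.

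**Figure D3:**
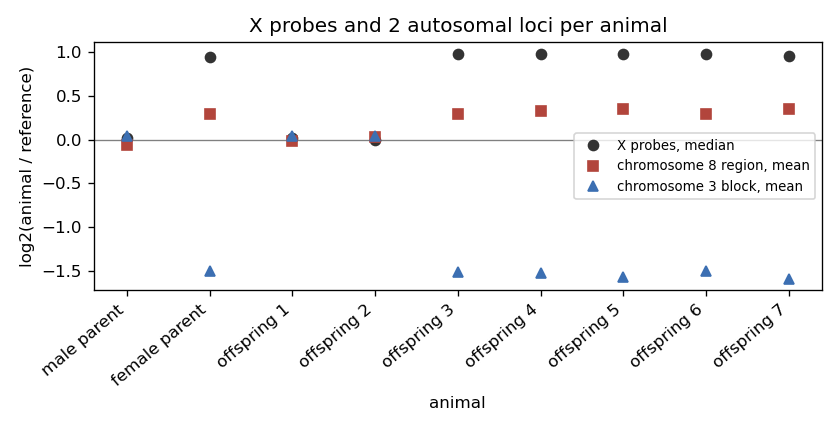
Log2 ratio of animal over reference (vertical axis) in each of the 9 animals: median of the 48 X probes (circles), mean of the chromosome 8 region from 102235347 (squares) and mean of the chromosome 3 block from 25432440 (triangles). The female parent and offspring 3 to 7 lie at 0.95 to 0.98 on X probes and at -1.50 to -1.59 in the chromosome 3 block.

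Among merged regions the parents differed in 137, and the female parent was higher in 136 of these. The 10 with the largest difference were all gains of 248 to 601 bp. With 2 components removed their differences were 0.01 to 0.11, a fall that this removal largely builds in. They were chromosome 18, 59288466 to 59289066 (difference 0.88) and 21921144 to 21921658 (0.75), chromosome 6, 47223495 to 47223905 (0.87), chromosome 5, 127019786 to 127020209 (0.80) and 50895458 to 50895928 (0.77), chromosome 13, 34615868 to 34616115 (0.78), chromosome 2, 98703221 to 98703551 (0.78), chromosome 11, 45162030 to 45162528 (0.77), and chromosome 15, 92612514 to 92613045 (0.77) and 11267875 to 11268179 (0.75). At the first, offspring 2 was at 1.03, the female parent at 0.80, offspring 7 at 0.61, offspring 1 at 0.30 and offspring 6 at 0.14, while the male parent and offspring 3, 4 and 5 lay between -0.11 and -0.07.

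Transmission was examined by asking which parent each offspring resembled. Offspring 7 was nearer to the female parent in 137 of the 137 regions, offspring 2 in 134 and offspring 1 in 96, while offspring 3, 4, 5 and 6 were each nearer to the male parent in 108. Between them, 3 offspring were nearer to the female parent in 79 regions, 2 in 29 and all 7 in 17. No region passed the exact binomial test after adjustment: the lowest adjusted p was 0.126, and 17 regions had an unadjusted p of 0.0156, the smallest that 7 offspring allow. Averaged over those 17, the male parent lay at -0.44, offspring 1 and 2 at -0.21 and -0.16, the female parent at -0.09 and offspring 3 to 7 at -0.02 to 0.29, above both parents. Offspring 3 to 7 were scanned on later days than the other animals. This order also parts the animals with high X probes from the others. Scan day and X level are thus not separated from it. A minimum of 3 probes gave 187 regions past the threshold, of 510 in which the parents differed. Since no p can be smaller than 0.0156, the adjustment lets regions pass only where a large share of them has all 7 offspring nearer to the same parent. Neither count is thus evidence about a single region. The regions share their pattern over animals and are not independent.

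Segments of the offspring without a call of the same sign in either parent numbered 128, of which 124 were gains and 4 were losses. In 4 of them a parent had a call of the opposite sign. Offspring 5 held 99 of them, offspring 2 held 16, offspring 7 held 7, offspring 4 held 5 and offspring 3 held 1. In 22 of the 128, all in offspring 2 and 7, a parent was itself past 0.25 over the same probes although no segment was called in it. Without offspring 5 the count was 29, and with 2 components removed, an alternative chosen after seeing the data, it was 0. The components were the largest patterns over these same animals, so their removal largely fixes that fall. The 10 that differed most from the parents are given as the ratio of the offspring ± SD over probes. Offspring 3 had 0.35 ± 0.06 at chromosome 17, 41424141 to 41424376, where the male parent was at -0.83, but offspring 4 and 5 lay higher, at 0.44 and 0.71. Offspring 4 had 0.33 ± 0.06 at chromosome 15, 51743812 to 51744154, 0.39 ± 0.05 at chromosome 10, 58969350 to 58969685, where a loss of -0.44 was called in the male parent, and 0.42 ± 0.11 at chromosome 6, 40798224 to 40798596; at these offspring 5 lay higher, at 0.49, 0.63 and 0.58. Offspring 5 had 0.45 ± 0.12 at chromosome 4, 89664784 to 89665157, 0.49 ± 0.08 and 0.40 ± 0.10 at chromosome 12, 37155386 to 37155704 and 17321643 to 17322216, and 0.37 ± 0.16 at chromosome 1, 143180913 to 143181654. Offspring 2 had 1.07 ± 0.14 at chromosome 6, 47223495 to 47223905, and 1.03 ± 0.05 at chromosome 19, 50707675 to 50708107, where the female parent was at 0.81 and 0.73. In the 8 regions of offspring 3, 4 and 5 the male parent lay below the reference, between -0.83 and -0.36, so part of each difference comes from that parent. In each of these 8 regions both parents and offspring 1 and 2, scanned on day 1, lay below offspring 3 to 7, scanned on later days. The female parent lay above the male parent and offspring 1 and 2 in each of the 8. The animals with high X probes were thus also parted from the others without overlap. Scan day, X level and a difference from the parents can therefore not be told apart there.

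**Figure D4:**
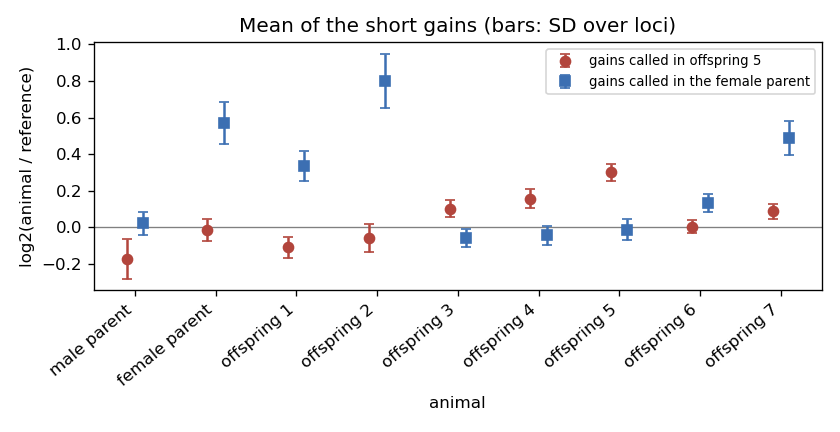
Mean log2 ratio (vertical axis) of each animal over the 87 gains called in the female parent and the 102 called in offspring 5, without those of the chromosome 8 region; bars are SDs over loci. In the first set offspring 2 is at 0.80, the female parent at 0.57 and offspring 3 at -0.06; in the second offspring 5 is at 0.30 and the male parent at -0.17.

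As groups, the offspring did not differ detectably from the parents: limma called 0 of 13607 blocks, with 851 at an unadjusted p under 0.05. With scan day as a block, an alternative chosen after seeing the data, 0 were called with 193 unadjusted, and within scan day 1 (both parents with offspring 1 and 2) 0 were called with 37 unadjusted. All parental arrays lay on slide 1, so slide and group could be separated only through a random block, which also called 0. Each animal against the other 8 gave 0 blocks after adjustment, with 7475 at an unadjusted p under 0.05, of which 3192 were in offspring 5, 2228 in offspring 2 and 1488 in the male parent. Blocks of 5 probes gave 3 calls. With an arm of 1 animal, simulated shifts of 0.15 were recovered in 0% of blocks, so a difference of that size was not detectable. The unadjusted count of these tests runs over all animals, so a block can enter it more than once and 13607 is not its total.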

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

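All tests of explanations in this part were chosen after the results had been seen. Among 35 sets of 7 offspring values, 3 had an animal standing apart from the others, where chance gives about 1 in 20. At chromosome 14, 54176697 to 54182168, offspring 1 was at -0.43, and the nearest other offspring at -0.58. Part of this gap came from the probe from 54178846, where offspring 1 was at 0.10 and the other offspring at -0.76 to -0.47. Offspring 2 had 43 losses, and the next offspring 11. Offspring 5 had 99 segments without a parental call of the same sign, and the next offspring 16.

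The 48 X and 3 Y probes, outside the comparisons of the report, gave a signal. The offspring median was 0.97 on X probes, against 0.02 in the male parent, and -4.55 on Y probes, against 0.05. By animal, X medians were 0.95 to 0.98 in the female parent and offspring 3 to 7, and 0.00 to 0.02 in the male parent and offspring 1 and 2. Y medians were -4.92 to -3.95 in the former and -0.02 to 0.11 in the latter. Offspring 3 to 7 thus had the levels of the labelled female, and offspring 1 and 2 those of the labelled male. The offspring medians therefore reflect sex and mark no change in the progeny by themselves. The sex of the offspring is not in the labels used. At 1 of the Y probes the DNA of the 6 animals with high X probes was not well above background on either array, so the size of its ratio is a bound. The same held in offspring 4, 5 and 6 at the Y probe from 784163, which sets the Y medians of these animals.

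In the first pattern, that of the short gains, the 87 called in the female parent lay on 18 chromosomes. Of these loci, 98.9% had a profile over the other 8 animals that correlated above 0.9 with loci on other chromosomes. This argues against independent segregation of inherited copy number. The parents, on the same slide and scan day, differed by 0.55 ± 0.15 (SD over loci). Part of that difference is fixed, since the loci were chosen as gains of the female parent. Offspring 1 and 2, not used in that choice, also shared a slide and scan day and lay at 0.33 and 0.80. These levels argue against slide or scan day as the only cause. Centring each probe length left 98.9% of the gains called, against probe length, while 98.1% of the sum of squares lay in 1 component, consistent with a strength per animal acting on the same sequences, such as may arise in DNA preparation. In offspring 2 the mean gain 100 to 200 bp from the centre was 0.77, near the central 0.80, but the probe minimum of the calls fixes such a width, so this leaves longer labelled fragments open. Over the 102 gains called in offspring 5, 74.5% of loci shared their profile in the same way. Offspring 5 exceeded offspring 6, on the same slide, by 0.30 ± 0.05 (SD over loci). This difference is largely fixed, since the loci were chosen as gains of offspring 5. In this set the animals of scan day 1 had means of -0.17 to -0.01, and those scanned later 0.00 to 0.30. The female parent, at -0.01, lay above the other animals of day 1, so the means also part the animals with high X probes from the rest. Scan day and X level are thus not separated from these levels. What differs between the animals' DNAs stays open, and an inherited difference that acts on many loci together was not tested.

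The second pattern is the stretch of chromosome 14 that was lower in all 9 animals. Its mean of -0.46 ± 0.02 (SD, n = 9) may reflect more copies in the reference mouse alone, or fewer copies in both parents and all offspring. These cannot be told apart, because every array used the same reference. The stretch was not at 1 level: its candidate regions ranged from -0.83 ± 0.04 (53752398 to 53764803) to -0.13 ± 0.03 (54370775 to 54371399). Why they differ was not tested. Loss or rearrangement in part of the cells, which also lowers or raises a ratio, was not tested. Dim probes are argued against: over the 158 probes well above background on all arrays the mean was -0.51 ± 0.01.

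The third pattern is that of autosomal regions which follow the sex chromosome probes. Each of the 6 animals with high X probes, including the female parent of scan day 1, exceeded each of the other 3 in the chromosome 8 region from 102235347, with a gap of 0.26, and lay below them in the chromosome 3 block from 25432440, with a gap of 1.54. Sequence shared with the X or the Y chromosome stays open for both, since these gaps restate the match that prompted the tests, and sequences were not compared. In the chromosome 3 block a loss inherited from the female parent is argued against where the male parent has equal copies on both chromosomes, since a paternal copy leaves at least -1 and the highest of the 5 offspring with low Y probes was at -1.50 ± 0.35 (SD over probes). A chromosome 8 gain inherited from the female parent also stays open: 3 merged regions, all in 1 candidate region, matched the X probes in 7 of 7 offspring. Chance gives 1.05 among 135 candidate regions if they segregate independently. The regions share patterns over animals and are not independent, so the comparison with this number cannot decide the question.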

How the results depend on the processing

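For offspring against the reference, leaving out each offspring gave 21 to 29 blocks against 23. Arrays with the animal in Cy3 or Cy5 alone gave 6509 and 4555, since a dye effect does not cancel in them by construction; blocks of 5 probes gave 43. For each animal against the other 8, Cy3 alone gave 6 and blocks of 5 probes gave 3, against 0. For offspring against parents, all alternatives run gave 0. Called segments, 572, became 1572 and 342 at thresholds of 0.15 and 0.4, and 2369 and 27 with at least 3 and 10 probes. The 128 segments without a parental call of the same sign became 620 and 18 at those thresholds, 979 and 1 at those minimums, 215 with a penalty of 4, and 29 to 128 without each offspring, the 29 without offspring 5. The parents differed in 486 blocks of 5 probes and 27 of 20 probes, against 138. A minimum of 3 probes took transmission from 0 to 187 regions. Whether any region can pass depends on the share in which all offspring are nearer to the same parent, and why that share changed was not tested. Removing 2 components, chosen after seeing the data, left 0 such segments and 3 blocks between parents (1 higher, 2 lower), brought the 10 named differences between parents to 0.01 to 0.11, and turned the difference from the parents to -0.028 at chromosome 4, 89664784, -0.035 at chromosome 12, 17321643, -0.11 at chromosome 6, 47223495, and -0.074 at chromosome 19, 50707675. The components were taken from these same animals, so the changes with their removal are largely built in and are no test of the calls. Apart from this and the single orientations, the cause was not tested. Of 260 values of named regions under signal alternatives, 217 moved by less than their spread, 39 by more, and 4 turned. Of these, 16 of the 39 and all 4 that turned came with 2 components removed, where the change is largely built in. Leaving animals out of the count of calls gave 439 to 565, with 71 losses against 114 without offspring 2, and joining neighbouring segments gave 734. The correction for base composition and the gene lists were not run, and transmission with 2 components removed had no regions left. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers.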

Other observations

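Over the loci called in the female parent, the ratio of offspring 2 fell with distance from the segment's centre, with a wide spread over loci: 0.59 ± 0.33 (SD over loci) at 200 to 300 bp, 0.36 ± 0.35 at 300 to 400 bp, 0.13 ± 0.21 at 400 to 600 bp and 0.01 ± 0.09 at 800 to 1200 bp. Of these loci, 60.9% had their centre in the middle 20% of the probes of their candidate region. Of the 87 loci, 72 overlapped a gain called in offspring 2, 66 one in offspring 7, 59 one in offspring 1, and none one called in offspring 3, 4, 5 or 6.

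Blocks without overlap between the 6 animals with high X probes and the other 3 made up 14.9% of 13607, where chance gives 2.38%, but neighbouring blocks are not independent, and the 3 animals with low X probes were all scanned on day 1, with the female parent as the only other animal of that day, so X level and scan day are nearly confounded in this share. The gap exceeded 0.1 in 10 blocks: 4 on chromosome 8, 2 on chromosome 3, and 1 each on chromosomes 6, 11, 12 and 15.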
